A study of Mus musculus with 486 samples.

How the data were processed

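Single mouse bone marrow cells and small pools of cells had been sorted into 96-well plates, reverse transcribed and pre-amplified with a set of TaqMan assays, and read on a Fluidigm BioMark microfluidic chip, per the labels' protocols. The deposited values are cycle threshold (Ct) values, the PCR cycle at which an assay's fluorescence passes a threshold, so that a lower Ct means more template and 1 cycle is a doubling at full PCR efficiency. This reading of the unit comes from the labels' protocols and from the values, which ran from 4.69 to 28.1 with a separate block at exactly 40. The value 40, held by 46.8% of all 23328 values, was taken as no Ct recorded. The instrument software, its version, its quality thresholds and any normalisation are not given in the sources used here. The series text speaks of 96 TaqMan assays, and the deposited table holds 48, of which 1 is a spike-in RNA added to every well. No assay for Ly6d, which was used for sorting, was analysed here.

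The table held 486 wells on 11 plates. The labels placed 464 of them in 6 sorted groups of single cells, 10 as wells of 10 cells, and 10 as wells of 20 cells. Another 2 wells carry a title that marks them as controls without reverse transcriptase and a description that calls them cells. They entered no comparison. Every group but 1 was spread over 2 plates, and no plate held single cells of more than 1 group, so a plate difference within a group is visible while the plates of different groups cannot be told apart from the groups. Groups were taken from the labels, which name no animal or culture. A group of cells was therefore treated as 1 sample, and no p-value was computed between groups of single cells.

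An assay counted as detected in a cell when a Ct was recorded and was at most 28. Cells entered the comparisons when at least 2 of the 3 reference assays, among them Atp5a1 and Hprt, were detected, which left out 1 cell and kept 463, with 40 to 45 cells per plate. Gene symbols follow the file's assay names, updated where the file used an older name (OCAB for Pou2af1, TDT for Dntt, E4BP4 for Nfil3, CD122 for Il2rb, NK1.1 for Klrb1c, CD157 for Bst1, BCL.XL for Bcl2l1). The assays named TCF and PTPCR kept the file's names. Values of 2 assays are not reported here, although both stay in the counts and means over assays. For the number of B-cell progenitor markers per cell, 4 of the fixed markers were used, a choice made after the values had been seen. No genome coordinates are given, because the files name no genome build.

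For each group the share of cells with an assay detected was computed with its exact (Clopper-Pearson) 95% interval and its value on each plate. The 95% interval of a difference between 2 shares follows Newcombe's method. Where an assay was detected in 0 cells, the limit given is 3 cells of the number examined, which lies below the upper bound of the exact interval. All these intervals and limits cover counting error only, not differences between animals, sorts or plates. An assay was called higher or lower when the share differed by at least 20 percentage points and every plate of one group lay on the same side of every plate of the other. By chance alone, 2 plates separate fully from 2 others in 33.3% of arrangements, and 2 plates from 1 in 66.7%. Between plates of the same group, the median gap in a share was 2.38 points over 225 assay and group pairs, the 95th percentile was 17.2 points, and 7 pairs differed by at least 20 points. Among the 107 pairs with a share between 5% and 95%, where plates have room to differ, the 95th percentile was 20.5 points, above the 20 points of the calling rule. Levels were compared among detecting cells as differences of mean Ct in cycles, for assays detected in at least 50% of cells of both groups, with a rule of at least 1 cycle and full separation of plates. Gfra2 and Bst1 had been used for sorting and were read as a check of the labels, which left 45 assays that could be counted. Named genes were, for each comparison, the 12 assays with the largest differences among those that met the rule in each direction, up to 4 members of each fixed gene list by size of difference, given as values, and the reference assays, apart from the assays not reported. Lists covered B-lineage transcription factors, pre-B cell receptor and B-cell signalling, V(D)J recombination, T-lineage and Notch, NK and innate lymphoid, dendritic cell, granulocyte-monocyte, erythroid-megakaryocyte, stem and multipotent progenitor, early lymphoid progenitor, cell cycle, and survival genes. No member of the dendritic cell, erythroid-megakaryocyte or cell cycle list was among the assays. The rule of size, the detection limit, the lists, the comparisons and most alternatives were fixed before the data were examined.

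The 10-cell and 20-cell wells were compared with a two-sided permutation test over wells (100000 resamples), and, as an alternative, with an exact sign-flip test over the 10 plates that each held 1 well of both kinds (1024 sign patterns). The shared plate pairs these wells by design. These p-values measure only the spread between wells, which may be technical. In the permutation test that spread also holds differences between plates and the sorted groups on them, which the sign-flip test within plates removes. Alternatives for the single cells were detection limits of Ct 24, 26, 30 or any recorded Ct, no filter or a stricter filter on cells, leaving out wells at positions 30, 36, 42 and 48, equal weight for plates, detection relative to the reference assays, rules of 15 or 30 points, no plate condition, and leaving out each plate in turn. Detection relative to the reference assays lowered the Ct limit in cells with a lower mean reference Ct. It also left out the cells with the highest mean reference Ct, which kept 347 of 463 cells. A limit of Ct 18, cells in the middle 50% of the mean reference Ct, and counting both wells titled as lacking reverse transcriptase as cells were added after the data had been seen.

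The calling rule was tested on simulated data with the real numbers of cells per plate and a plate-to-plate SD of 4.29 points, over 45 assays and 200 simulations for each comparison. For the Bst1 comparison, with 1 plate on one side, the rule called 85.2% of assays with a true difference of 30 points, 98.3% at 40 points, and 1.73% of assays with none. For the Gfra2 comparison in FrA these shares were 91.3%, 99.4% and 0.589%. For the Ly6d comparison in CLP they were 91.9%, 99.7% and 0.422%, and for the Gfra2 comparison in CLP 91.4%, 99.4% and 0.667%. Assays detected in almost no or almost all cells were simulated without plate noise and can hardly be called when no difference is present. The rates with no difference are therefore too low for assays with room to move. The plate noise came from plates of the same group, so differences between sorts or animals were not simulated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.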

Results

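Expression of 47 genes was measured by RT-qPCR in single bone marrow cells of wild-type C57/Bl6 mice from early lymphoid compartments. Common lymphoid progenitors (CLP), which can still give rise to several lymphoid lineages, had been sorted into 3 groups by the surface proteins Ly6d and Gfra2, a receptor for GDNF-family ligands. Cells of the FrA compartment, an early stage of B-cell development, had been sorted into 3 groups by Gfra2 and Bst1, a cell-surface ADP-ribosyl cyclase. The comparisons address how far these markers divide the compartments into cells with and without a B-lineage programme. After filtering, the CLP groups held 87 Ly6d-Gfra2- cells, 86 Ly6d+Gfra2- cells and 82 Ly6d+Gfra2+ cells. The FrA groups held 83 Gfra2-Bst1- cells, 83 Gfra2+Bst1- cells and 42 Gfra2+Bst1+ cells, the last from a single plate. Each group is 1 sample, so differences between groups carry no test between animals, and the intervals given cover counting error only.

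Transcripts of both sort genes on the panel were read first, as a check of the labels. Gfra2 was detected in 93.9% of Ly6d+Gfra2+ CLP (95% interval 86.3 to 98) against 9.30% of Ly6d+Gfra2- CLP (4.10 to 17.5), and in 91.6% of Gfra2+Bst1- FrA against 13.3% of Gfra2-Bst1- FrA. Bst1 was detected in 88.1% of Gfra2+Bst1+ FrA (74.4 to 96.0) and in 34.9% of Gfra2+Bst1- FrA (24.8 to 46.2). The mean number of gene assays detected per cell was 22.0 ± 1.98 (SD over cells) in Ly6d-Gfra2- CLP, 22.4 ± 2.40 in Ly6d+Gfra2- CLP, 26.1 ± 2.95 in Ly6d+Gfra2+ CLP, 21.8 ± 3.15 in Gfra2-Bst1- FrA, 26.5 ± 2.69 in Gfra2+Bst1- FrA and 27.7 ± 2.98 in Gfra2+Bst1+ FrA. The mean Ct of the 3 reference assays, which falls as RNA input rises, was lowest in Ly6d-Gfra2- CLP at 11.22 cycles and highest in Gfra2-Bst1- FrA at 12.62 cycles. It lay between 11.75 and 12.24 cycles in the other groups. Of the reference assays, Atp5a1 was detected in 100% of cells of every group and Hprt in 90.4% to 100%. Il7r and Ikzf1, both on the early lymphoid list, were detected in 97.6% to 100% and did not meet the rule in any comparison. The spike-in Ct ranged between plates from 6.63 to 10.08 cycles, and both of these plates held Ly6d+Gfra2+ CLP.

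**Figure D1:**
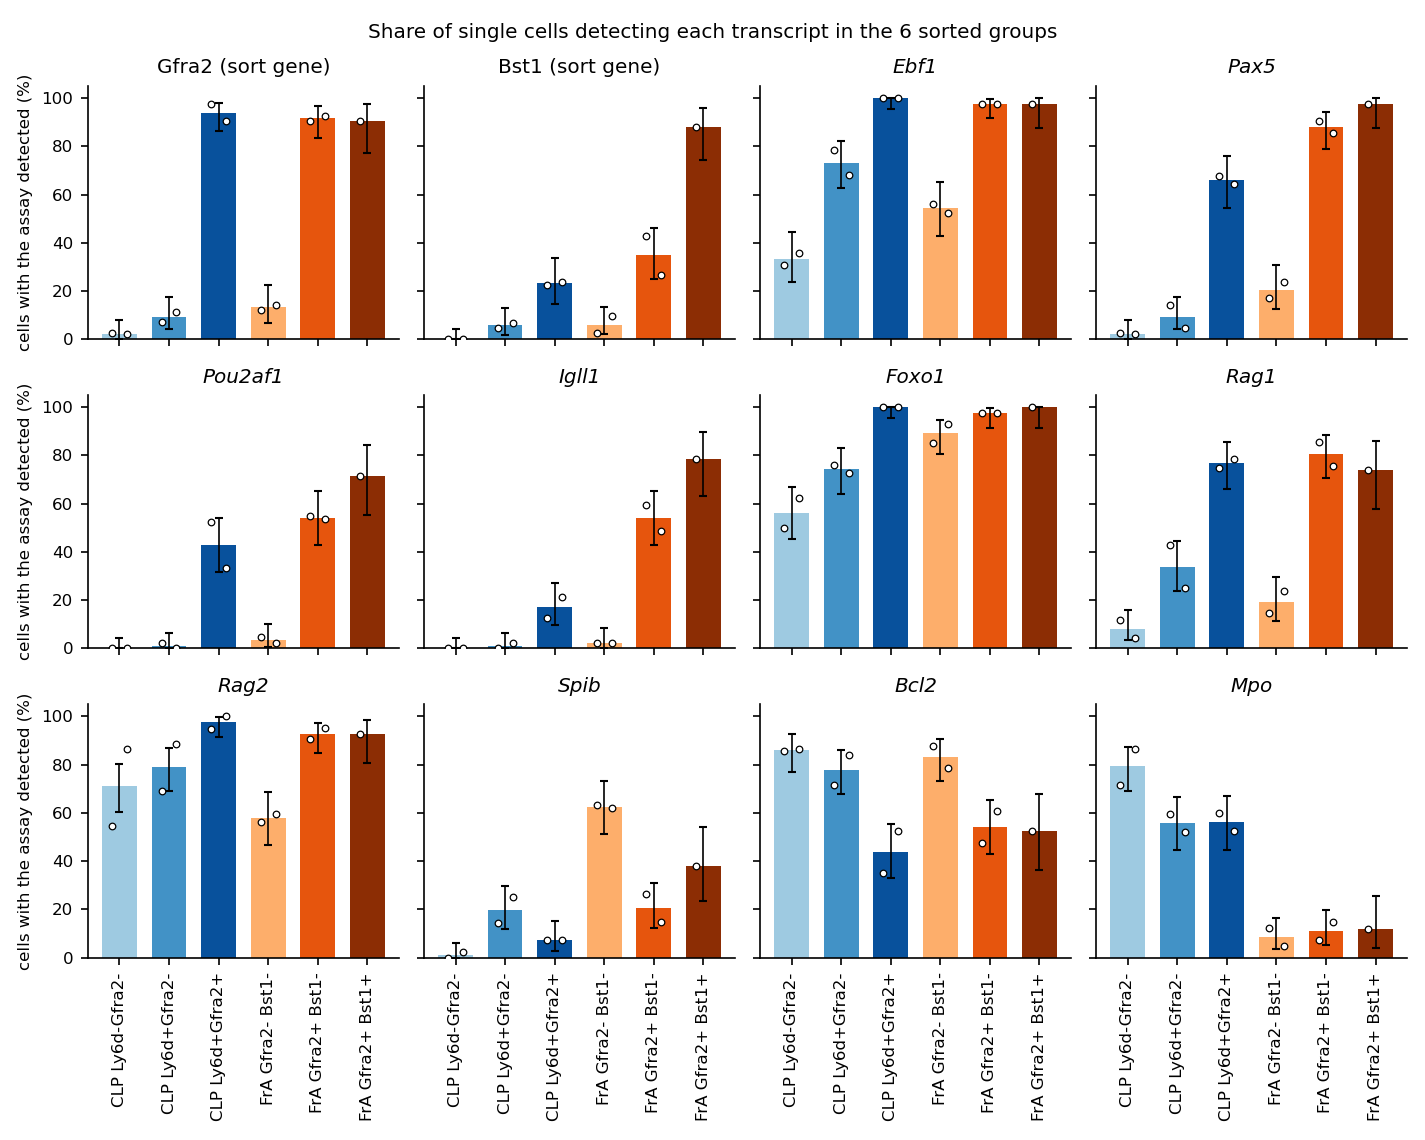
Share of single cells (%) in which each of 12 transcripts was detected, for the 6 sorted groups. Bars are shares over all cells of a group, error bars are exact 95% intervals for counting error, and open circles are single plates. Ebf1 goes from 33.3% to 73.3% to 100% across the CLP groups, and Spib is highest in Gfra2-Bst1- FrA at 62.7%.

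Gain of Ly6d within Gfra2- CLP went with more cells expressing Ebf1, a transcription factor that specifies the B lineage, and Rag1, a subunit of the V(D)J recombinase. Ebf1 was detected in 73.3% of Ly6d+ cells (62.6 to 82.2) against 33.3% of Ly6d- cells (23.6 to 44.3), and Rag1 in 33.7% against 8.05%. Mpo, the myeloperoxidase of granulocyte precursors, was detected in 55.8% of Ly6d+ cells (44.7 to 66.5) against 79.3% of Ly6d- cells (69.3 to 87.3), and Nfil3, a transcription factor needed for NK and innate lymphoid cells, in 39.5% against 62.1%. These 2 higher and 2 lower assays were the only ones of 45 to meet the rule, whose condition of full separation of plates is met by chance in 33.3% of arrangements of 2 plates against 2. The count of higher assays was 4 without plate 9, and that of lower assays was 4 without plate 7. Of 8 B-lineage transcription factors on the panel, 1 was higher. Spib and Foxo1 were detected in 19.8% against 1.15% and 74.4% against 56.3%, differences below the rule of 20 points. None of 3 pre-B receptor and signalling genes met the rule, and Igll1, the surrogate light chain lambda 5, was detected in 1.16% against 0 of 87 cells, which allows a share of up to 3.45%. Kit, the stem cell factor receptor, was detected in 79.1% against 96.6%. None of 5 T-lineage genes met the rule. Gata3 was detected in 6.98% against 17.2%.

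Among detecting cells, 2 of 22 assays had a lower level in Ly6d+ cells. For Mpo, the mean Ct was 14.59 ± 1.19 cycles (SD, 48 cells) against 13.41 ± 1.43 cycles (69 cells). The mean Ct was 11.55 against 10.59 cycles for Atp5a1 and 14.09 against 13.26 cycles for Hprt, neither of which met the rule. Relative to the mean of the reference assays neither of the 2 level calls was left, and Foxo1, Il7r and Rag2 met the rule for a higher level in Ly6d+ cells (1.55, 1.45 and 1.03 cycles). The Mpo share on plates ran from 52.3% to 59.5% in Ly6d+ cells and from 71.4% to 86.7% in Ly6d- cells, and the Mpo call was lost without plate 7 (-19.8 points) and without plate 9 (-15.6 points). The Rag1 call was lost without plate 6 (17.0 points), and no level call was left without plate 9.

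Gain of Gfra2 among Ly6d+ CLP went with detection of 4 of 8 B-lineage transcription factors in more cells. Pax5, the B-lineage commitment factor, was detected in 65.9% of Gfra2+ cells (54.6 to 76) against 9.30% of Gfra2- cells (4.10 to 17.5), and Pou2af1, a B-cell coactivator, in 42.7% against 1.16%. Ebf1 and Foxo1, a forkhead factor acting with Ebf1, were detected in 100% of Gfra2+ cells against 73.3% and 74.4%. Rag1 was detected in 76.8% against 33.7%, and Nfil3 in 62.2% against 39.5%. Bcl2, an inhibitor of apoptosis, was the 1 assay that met the rule for fewer Gfra2+ cells, at 43.9% (33.0 to 55.3) against 77.9% (67.7 to 86.1). The count of lower assays was 3 without plate 1 and 2 without plate 6. Lck, a Src-family kinase, was detected in 52.4% against 72.1% and Spib in 7.32% against 19.8%, both under 20 points apart.

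By list, 4 of 8 B-lineage transcription factors and 1 of 3 V(D)J genes were higher, and 0 of 3 pre-B receptor and signalling genes met the rule. Igll1 was detected in 17.1% against 1.16%. Rag2 was detected in 97.6% against 79.1%, and Dntt, the terminal transferase, in 100% against 97.7%. Of 3 granulocyte-monocyte genes none met the rule, and Mpo was detected in 56.1% against 55.8%. Of 4 NK and innate lymphoid genes Nfil3 alone was higher, and Klrb1c, the NK1.1 antigen, was detected in 26.8% against 11.6%. Of 3 survival genes 1 was lower. Among 23 assays compared for level, Ebf1 was higher by 1.84 cycles, Foxo1 by 1.37 cycles and Cd24a, a surface antigen of developing B cells, by 1.06 cycles in Gfra2+ cells. The reference assays Atp5a1 and Hprt differed by 0.02 and 0.07 cycles. Relative to the reference assays Cd24a differed by 0.75 cycles and no longer met the rule, and without plate 1 only 1 of these level calls was left, for Ebf1. The Nfil3 detection call was lost without plate 1 (15.2 points) and at a limit of Ct 18 (14.5 points), a limit at which the Pou2af1 difference was 0.

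In FrA, gain of Gfra2 went with detection of Pax5, Rag1, Igll1 and other genes of B-cell development in more cells. Pax5 was detected in 88.0% of Gfra2+Bst1- cells (79 to 94.1) against 20.5% of Gfra2-Bst1- cells (12.4 to 30.8), Rag1 in 80.7% against 19.3%, Igll1 in 54.2% against 2.41%, Pou2af1 in 54.2% against 3.61%, Ebf1 in 97.6% against 54.2% and Rag2 in 92.8% against 57.8%. Gfra1, a paralog of Gfra2, was detected in 83.1% against 53%, Kit in 88.0% against 65.1% and Bcl2l1, which encodes the apoptosis inhibitor Bcl-xL, in 59% against 37.3%. In the other direction, Spib, an Ets-family factor of B and plasmacytoid dendritic cells, was detected in 20.5% of Gfra2+ cells (12.4 to 30.8) against 62.7% of Gfra2- cells (51.3 to 73), and Bcl2 in 54.2% against 83.1%. Thus 9 assays were higher and 2 lower of 45.

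Of the 8 B-lineage transcription factors 3 were higher and 1 lower, of 3 V(D)J genes 2 were higher, and of 3 survival genes 1 was higher and 1 lower. None of 5 T-lineage genes and none of 4 NK and innate lymphoid genes met the rule. Il2rb, a subunit of the IL-2 and IL-15 receptors, was detected in 1.20% against 20.5%, and Klrb1c in 26.5% against 7.23%, both under 20 points apart. Mpo was detected in 10.8% against 8.43%. Among 22 assays compared for level, 8 were higher in Gfra2+ cells and none lower. The differences were 2.96 cycles for Ebf1, 2.83 for Cd24a, 1.85 for Dntt, 1.82 for Rag2, 1.78 for Foxo1, 1.28 for the reference gene Hprt, 1.25 for Spi1 and 1.15 for Kit. Reference input moved with this comparison, since the mean reference Ct was 11.75 cycles in Gfra2+Bst1- FrA and 12.62 cycles in Gfra2-Bst1- FrA, with Atp5a1 0.81 cycles apart, and the mean spike-in Ct was 6.70 against 7.48 cycles. Relative to the reference assays 2 level calls were left, for Ebf1 (1.91 cycles) and Cd24a (1.95 cycles), and Bcl2 met the rule for a lower level (-1.03 cycles). Without that scaling Bcl2 differed by -0.09 cycles. In cells from the middle 50% of the reference Ct, an alternative chosen after seeing the data, 6 of the 9 higher assays and both lower assays still met the rule, while Gfra1 (21.6 points, plates not separated), Kit (19.8 points) and Bcl2l1 (17.0 points) did not. The Gfra1 call was also lost without plate 3 (15.3 points), and the Pou2af1 difference was 0 at a limit of Ct 18.

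Across the Gfra2 step, 4 assays were higher in both compartments (Ebf1, Pax5, Pou2af1 and Rag1) where 1.20 would be expected from independent lists of 6 and 9 among 45, and Bcl2 was lower in both. That expectation is too low, since assays at 0%, such as Ret and Bcl11b, or at 100%, such as Atp5a1 and Ikzf1, could not meet the rule. Without plate 1, 7 assays were higher in both. Both comparisons used separate cells and plates. No assay met the rule in opposite directions. The step was larger in FrA than in CLP by 35.9 points for Igll1 and by 25.0 points for Bcl2l1. For Spib, the difference between Gfra2+ and Gfra2- cells was -12.5 points in CLP and -42.2 points in FrA. These differences between compartments were not tested.

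**Figure D2:**
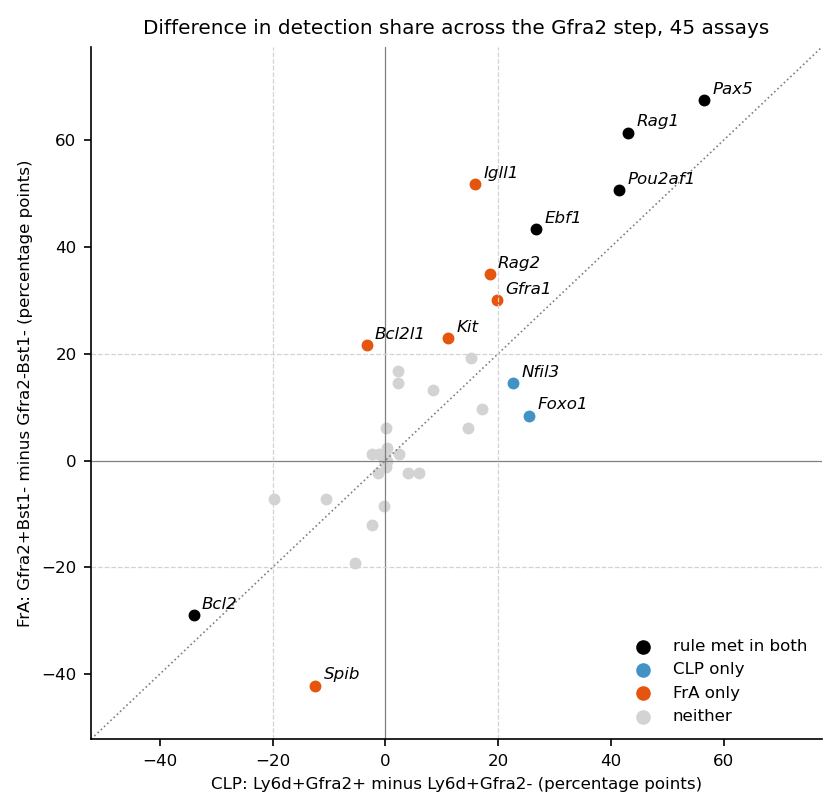
Difference in detection share (percentage points) between Gfra2+ and Gfra2- cells in CLP (horizontal) and in FrA (vertical) for 45 assays, with dashed lines at 20 points and a dotted line of equal differences. Black points met the rule in both compartments, and Igll1 and Spib lie far from the line of equal differences.

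Gain of Bst1 among Gfra2+ FrA went with detection of Igll1 in more cells. Igll1 was detected in 78.6% of Bst1+ cells (63.2 to 89.7) against 54.2% of Bst1- cells (42.9 to 65.2), and Gfra1 in 61.9% (45.6 to 76.4) against 83.1% (73.3 to 90.5). Of 45 assays 2 were higher and 1 lower, and none of the 8 B-lineage transcription factors met the rule. Pax5 was detected in 97.6% against 88.0%, Pou2af1 in 71.4% against 54.2%, Spib in 38.1% against 20.5% and Ebf1 in 97.6% of both. None of 3 V(D)J genes met the rule, with Rag1 at 73.8% against 80.7% and Rag2 at 92.9% against 92.8%. In detecting cells Igll1 was higher by 1.87 cycles and Pax5 by 1.39 cycles in Bst1+ cells. Mean Ct values of Notch1, 17.01 against 15.90 cycles, Spi1, 15.93 against 14.90 cycles, and Dntt, 19.79 against 18.55 cycles, met the rule for a lower level. Atp5a1 and Hprt differed by -0.09 and 0.11 cycles, while the mean spike-in Ct was 8.35 cycles on the Bst1+ plate against 6.70 cycles in Bst1- cells.

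The Bst1+ group came from 1 plate, so these differences carry no check between plates on that side, and chance alone separates 2 plates from 1 in 66.7% of arrangements. The Gfra1 call was lost without plate 3 (-6.39 points) and without well positions 30, 36, 42 and 48 (-19.0 points), the Igll1 detection call without plate 4 (19.0 points) and in cells from the middle 50% of the reference Ct (15.6 points), of which the Bst1+ group had 15, and the Igll1 level call without plate 3. Of the lower levels, Spi1 lost its call relative to the reference assays (-0.84 cycles), Spi1 and Dntt lost theirs without plate 3, and Notch1 without plate 4.

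Between compartments, Gfra2+Bst1- FrA differed from Ly6d+Gfra2+ CLP mainly in Igll1, Pax5 and Mpo. Igll1 was detected in 54.2% of FrA cells (42.9 to 65.2) against 17.1% of CLP (9.66 to 27.0), and Pax5 in 88.0% against 65.9%. Mpo was detected in 10.8% of FrA cells (5.08 to 19.6) against 56.1% of CLP (44.7 to 67). Ebf1, Rag1 and Rag2 were detected in 97.6%, 80.7% and 92.8% of these FrA cells against 100%, 76.8% and 97.6% of CLP. Id2, an inhibitor of E-proteins, was detected in 28.9% against 47.6%. Among 25 assays, Bad and Cd24a had a higher level in FrA by 1.1 and 1.06 cycles, and neither call was left relative to the reference assays, with medians in place of means, or without plate 10. The mean spike-in Ct was 6.70 against 8.40 cycles. Relative to the reference assays Dntt met the rule for a lower level (-1.14 cycles). Bad also lost its call without plate 3 and Cd24a without plate 4, and the Pax5 detection call was lost without plate 3 (19.5 points).

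Between the Gfra2- groups, Spib was detected in 62.7% of Gfra2-Bst1- FrA (51.3 to 73) against 19.8% of Ly6d+Gfra2- CLP (12.0 to 29.8), and Id3, another E-protein inhibitor, in 26.5% against 3.49%. Mpo was detected in 8.43% (3.46 to 16.6) against 55.8%, Id2 in 36.1% against 58.1% and Rag2 in 57.8% against 79.1%. Ebf1 was detected in 54.2% against 73.3% and Rag1 in 19.3% against 33.7%, both under 20 points apart. Mean Ct in detecting cells met the rule for a lower level in FrA for Dntt (20.40 against 18.29 cycles), Notch1 (16.42 against 14.83 cycles) and Rag2 (17.55 against 16.17 cycles), and none of 22 assays was higher. Relative to the reference assays the Rag2 level difference was -0.88 cycles and its call was lost. The mean reference Ct was 12.62 against 12.24 cycles, and the Rag2 detection call was lost without plate 2 (-19.5 points), without plate 7 (-11.2 points), relative to the reference assays (-18.6 points) and in cells from the middle 50% of the reference Ct (-13.3 points). The Id2 call was lost without plate 8 (-14.2 points) and relative to the reference assays. Detection relative to the reference assays also left out the cells with the highest reference Ct.

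Within single cells, 4 markers of B-cell progenitors were counted (Ebf1, Pax5, Igll1 and Pou2af1). At least 3 of them were detected together in 0 of 87 Ly6d-Gfra2- CLP, which allows a share of up to 3.45%, in 1.16% of Ly6d+Gfra2- CLP and in 42.7% of Ly6d+Gfra2+ CLP (31.8 to 54.1). In FrA they were detected together in 3.61% of Gfra2-Bst1- cells (0.752 to 10.2), 63.9% of Gfra2+Bst1- cells (52.6 to 74.1) and 90.5% of Gfra2+Bst1+ cells (77.4 to 97.3). The share in Ly6d+Gfra2+ CLP was 30.5% at a limit of Ct 24 and 15.9% at a limit of Ct 18, where that in Gfra2+Bst1- FrA was 48.2%. At least 2 assays of the wider B-lineage list were detected in 100% of cells of every group, so that this list did not separate them. At least 2 granulocyte-monocyte genes (of Mpo, Cebpa and Spi1) were detected beside them in 80.5% of Ly6d-Gfra2- CLP, 55.8% of Ly6d+Gfra2- CLP and 54.9% of Ly6d+Gfra2+ CLP, against 7.23%, 19.3% and 16.7% of the Gfra2-Bst1-, Gfra2+Bst1- and Gfra2+Bst1+ FrA groups. At least 2 T-lineage or NK and innate lymphoid genes were detected beside B-lineage genes in 88.0% to 97.7% of cells of the 6 groups. Since every cell met the B-lineage condition, these shares and those for granulocyte-monocyte genes equal the shares of the other list alone. Both lists hold a widely detected assay, Notch1 in 92.9% to 100% and Spi1 in 80.7% to 100% of cells. The shares therefore do not show programmes of several lineages in the same cell. Bcl11b, a T-lineage commitment factor, Gfra3 and Ret, the signalling partner of the Gfra receptors, were not detected in any of 463 cells, which allows a share of up to 3.45% in the largest group and 7.14% in the smallest. These limits hold only if the 3 assays work, which the data do not show, since no pooled well detected them either.

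**Figure D3:**
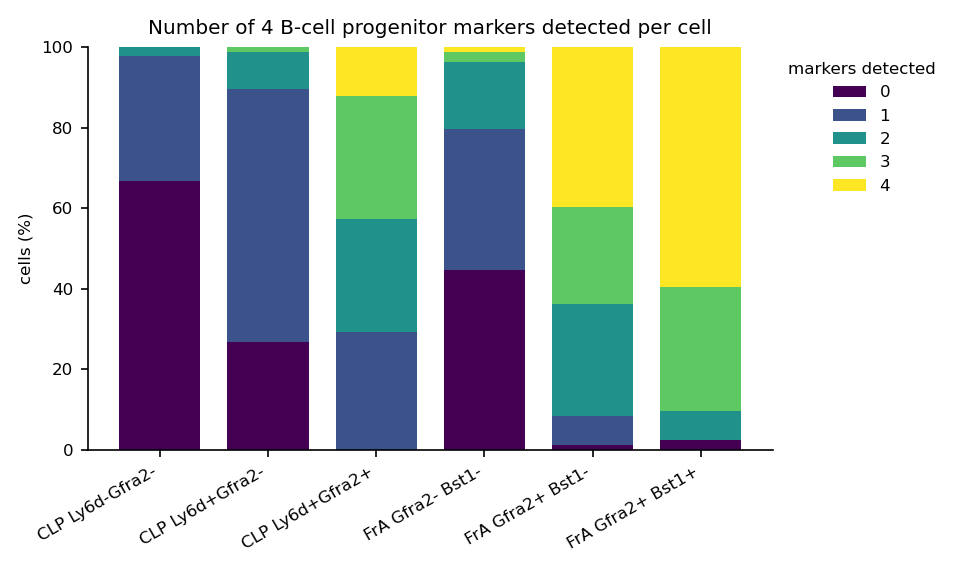
Share of cells (%) by the number of B-cell progenitor markers detected in the same cell (Ebf1, Pax5, Igll1 and Pou2af1), for the 6 sorted groups. In Gfra2+Bst1+ FrA 90.5% of cells had at least 3 markers, against 3.61% in Gfra2-Bst1- FrA.

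The pooled wells checked whether the readout followed input. Wells of 20 cells detected 37.3 ± 2.75 gene assays (SD, n = 10 wells) and wells of 10 cells 33.9 ± 3.31 (n = 10), a difference of 3.40 assays (two-sided permutation test, p = 0.0278), with more assays in the 20-cell well on 9 plates and equal numbers on 1. The mean Ct of the 24 assays detected in every pooled well was 9.75 ± 0.86 cycles against 10.84 ± 0.76 cycles, a difference of -1.09 cycles (permutation test, p = 0.00962), where a doubling of input is 1 cycle at full PCR efficiency. With wells paired by plate, both differences had p = 0.00391 in an exact sign-flip test. The spike-in Ct, which does not depend on the number of cells, differed by -0.03 cycles (permutation test, p = 0.953). The mean reference Ct was 3.07 ± 0.49 cycles lower in 10-cell wells than in single cells of the same plate (SD, n = 10 plates), against 3.32 cycles for 10 cells at full efficiency. For assays detected in under 50% of single cells of a group, the pooled wells gave 180 detections in 284 combinations of well and assay, and 179.6 would be expected if every pool were drawn at random from cells with the single-cell shares. Assays detected in more cells were left out of this count. Of those, Rag2 was detected in 3 of 4 pooled wells of Gfra2-Bst1- FrA and of Ly6d-Gfra2- CLP. Its shares in single cells were 57.8% and 71.3%, at which random pools would rarely miss it. The pools therefore did not follow the single-cell shares for every assay.

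**Figure D4:**
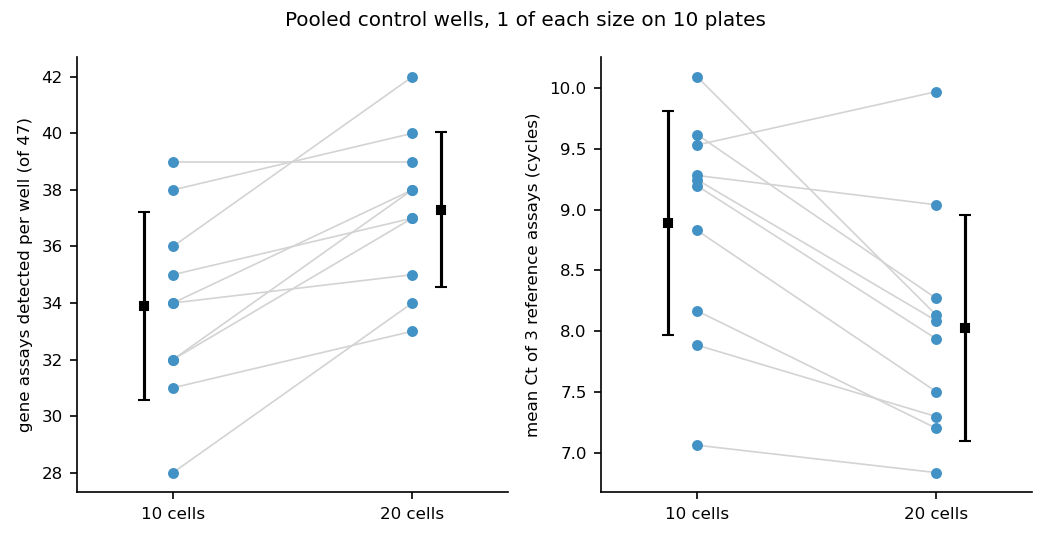
Gene assays detected per well (left) and mean Ct of 3 reference assays in cycles (right) in wells of 10 and 20 cells. Points are wells, grey lines join wells of the same plate, and squares with bars are means ± SD over 10 wells. The 20-cell wells detected 37.3 assays on average and the 10-cell wells 33.9.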

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

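The check on the wells titled as lacking reverse transcriptase was chosen only after their values were seen. On plate 8, among Gfra2-Bst1- FrA wells, 2 wells have a title that marks them as controls without reverse transcriptase, while their descriptions call them cells. They detected 26 and 25 gene assays with a mean reference Ct of 11.65 and 12.41 cycles, against 21.5 assays and 12.81 cycles on average in the single cells of that plate. No other wells without reverse transcriptase were analysed here, so there is no background measured in controls to set beside these values. Counting both as cells of their labelled group changed none of the counts of higher and lower assays. No biological explanation was tested.

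In the pooled wells, no well stood apart from the other 9 of its kind in the number of assays, the spike-in Ct or the Ct of each reference assay, in 10 checks of which about 1 in 20 would flag by chance. No assay moved in opposite directions across the Gfra2 step in CLP and FrA on all pairs of plates.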

How the results depend on the processing

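Tests at a limit of Ct 18, in the middle 50% of the reference Ct and with the wells titled as lacking reverse transcriptase were chosen after seeing the data. Share differences were recomputed for the called assays, and none changed direction. Of these values, 516 moved by less than the interval of the reported value and 6 by more. That interval is a lenient yardstick, since the alternatives reuse most of the same cells and some of them change very few values. Detection limits of Ct 24, 26 and 30 or any recorded Ct, no filter on cells, equal weight for plates, detection relative to the reference assays and no plate condition left every count of higher or lower assays within 1.5 times of its reported value, although relative detection ended the calls of Id2 and Rag2 between the Gfra2- groups. Relative detection also left out the cells with the highest reference Ct. Whether the scaling or the left-out cells ended these calls was not tested. The limits of Ct 30 and any recorded Ct add only 1 value, since 1 recorded Ct lay above 28. Pairing the 10- and 20-cell wells by plate cannot change the mean differences, 3.40 assays and -1.09 cycles. Only the p-value can change, and it was 0.00391 for both in the exact sign-flip test. The number of assays differed by 3.30 to 3.40 at limits of Ct 24, 26 and 30.

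A rule of 15 points gave 5 higher and 4 lower for the Ly6d step, 11 and 2 for the Gfra2 step in CLP, 4 and 2 for the Bst1 step, 2 lower from CLP to FrA among Gfra2+ and 5 lower among Gfra2- cells. A rule of 30 points gave 1 and 0, 3 higher in CLP, 1 lower for the Gfra2 step in FrA, 1 and 0 for Bst1, 1 higher among Gfra2+, and 1 and 1 among Gfra2- cells. These follow from the rule's size. Requiring every reference assay gave 2 lower assays each for the Gfra2 step in CLP and the Bst1 step, leaving out the 4 well positions gave 2 and 0, and a limit of Ct 18 gave 2 for the Bst1 step. The middle 50% of the reference Ct gave 4 higher for the Ly6d step and 2 lower among Gfra2+ cells. For these the cause was not tested.

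The share of cells with at least 3 B-cell markers in Ly6d+Gfra2- CLP was 0% at Ct 24, at Ct 18 and in the middle 50% of the reference Ct. It was 30.5% at Ct 24 and 15.9% at Ct 18 in Ly6d+Gfra2+ CLP, 48.2% at Ct 18 in Gfra2+Bst1- FrA, and 73.3% in the middle 50% for Gfra2+Bst1+ FrA, where co-detection with granulocyte-monocyte genes was 0%. Level counts relative to the reference assays were 3 higher and 0 lower for the Ly6d step, 2 and 1 for the Gfra2 step in FrA, and 0 and 1 among Gfra2+ cells, where medians also gave 0. For these too the cause was not tested.

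Leaving out each plate in turn gave 2 to 4 higher and 2 to 4 lower assays for the Ly6d step (4 without plate 9 and 4 without plate 7), 1 to 3 lower for the Gfra2 step in CLP (3 without plate 1, 2 without plate 6), 1 to 3 higher and 0 to 2 lower for Bst1 (1 and 2 without plate 4, 0 lower without plate 3), 1 to 4 higher and 1 to 2 lower among Gfra2+ cells (4 without plate 1, 1 without plate 3, 2 lower without plate 3 or 10), 2 to 5 lower among Gfra2- cells (5 without plate 2 or 7), and 4 to 7 higher in both compartments (7 without plate 1). Level counts ran from 0 to 6 lower for the Ly6d step (6 without plate 5, 1 without plate 6, 4 without plate 7, 0 without plate 9), 1 to 6 higher and 0 to 1 lower for the Gfra2 step in CLP (1 higher and 1 lower without plate 1, 6 without plate 10), 1 to 3 higher for Bst1 (1 without plate 3), and 0 to 8 higher and 0 to 1 lower among Gfra2+ cells (8 without plate 1, 1 without plate 3 or 4, 0 without plate 10, 1 lower without plate 3). Shares ran from 0% to 2.38% for at least 3 B-cell markers in Ly6d+Gfra2- CLP (0% without plate 6) and from 71.4% to 88.9% for co-detection in Ly6d-Gfra2- CLP (88.9% without plate 5). These ranges rest on fewer plates, and otherwise the cause was not tested. On simulated data with the real cell numbers, the rule called 85.2% to 91.9% of differences of 30 points.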

Other observations

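Tests on Ebf1 and Spib and on levels across the Gfra2 step in FrA were chosen only after those results were seen, as were the intervals used to read the reference Ct of wells with Mpo, while what both tests on Mpo would show was written down first.

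Within Gfra2-Bst1- FrA, cells divided by Ebf1 differed in other genes. Rag1 was detected in 16 of 45 cells with Ebf1 (35.6%, exact 95% interval 21.9 to 51.2) and in 0 of 38 cells without (which allows a share of up to 7.89%), Pax5 in 35.6% against 2.63%, Dntt in 100% against 63.2% and Rag2 in 73.3% against 39.5%. Lck was detected in 86.7% against 60.5%, Bach1 in 86.7% against 65.8% and Spi1 in 88.9% against 71.1%. Bad was detected in 44.4% against 65.8%, with an interval of the difference from -40.1 to 0.0908 points, and Bcl2 in 75.6% against 92.1%, from -31.7 to -0.0951 points. These genes were chosen after their values were seen. Cells with Ebf1 detected 22.8 assays on average with Spib and 23.1 without. Cells without Ebf1 detected 19.4 with Spib (33 cells) and 23.8 without (5 cells), so a general difference in detection was not separated from these genes.

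In this group Spib was detected less often in cells with Ebf1 than in cells without it, while 22.9% of all its cells had both. Spib was detected in 19 of 45 cells with Ebf1 (42.2%, 27.7 to 57.8) and in 33 of 38 without (86.8%, 71.9 to 95.6). Low RNA input would remove both transcripts together and so give a difference above 0, the opposite of the one seen. It was therefore no candidate for this pattern before any test. Among cells in the middle 50% of the reference Ct the share with Ebf1 minus the share without was still -35.2 points (95% interval -57.8 to -6.47). That value shows the relation within this range of input and is no evidence for another explanation. The 5 cells with neither transcript had a mean reference Ct of 11.58 cycles, against 12.52 to 12.82 cycles in the others. A difference between plates would leave no relation within them, and the mean difference within plates was -44.7 points (-62.4 to -27.1), with -63.2 points on plate 8 and -25.6 points on plate 2, where the interval reached 3.96. The 2 plates differed by only 3.72 points for Ebf1 and 1.51 points for Spib. A plate difference that small could not have made the pattern, so the mean within plates was no further test of it. This test had first required the interval of each plate to lie below 0, which plate 2 did not meet. It was reworded after the values were seen. Separately sorted Ly6d+Gfra2- CLP gave -38.3 points (-58.2 to -17.3), so 2 alternative states of these Gfra2- progenitors may account for the pattern, though Ly6d-Gfra2- CLP, with Spib in 1 of 87 cells, gave -1.72 points (-9.14 to 10.1). The relation could not be read in the Gfra2+ groups, where nearly all cells had Ebf1. Both transcripts were detected there in 38.1% of Gfra2+Bst1+ FrA, 18.1% of Gfra2+Bst1- FrA and 7.32% of Ly6d+Gfra2+ CLP. Spib without Ebf1 was detected in 0%, 2.41% and 0%, so the 2 transcripts are not mutually exclusive. Plasmacytoid dendritic cells within the gate stay open, since 0 of their fixed markers besides Spib were on the panel.

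Levels of 8 assays were higher across the Gfra2 step in FrA. If less RNA in Gfra2- wells were the whole cause, cells with matched input would differ by under 1 cycle. Among cells in the middle 50% of the reference Ct, the median difference over the 7 of these assays that are not reference assays was 1.63 cycles (quartiles 1.07 and 2.16), against 1.82 cycles in all cells. That median argues against less RNA as the whole cause, but only weakly. Input was not fully matched, since the mean reference Ct of these cells was 11.87 cycles in Gfra2+Bst1- FrA and 12.09 cycles in Gfra2-Bst1- FrA. The lower quartile thus lay close to 1 cycle with part of the input gap still in it. These assays had also been chosen for a difference of at least 1 cycle, Kit (0.84 cycles) and Spi1 (0.81 cycles) fell under it, and the median relative to the reference assays was 0.96 cycles. Over all 22 assays compared the median was 0.81 cycles, and -0.12 cycles relative to the reference assays, so less RNA could account for a general shift of that size. The mean spike-in Ct was 0.78 cycles higher on the Gfra2- plates, both of which lay above both Gfra2+Bst1- plates. Lower amplification efficiency there would give this, but the spike-in Ct did not follow the reference assays elsewhere. Across the Bst1 step it was 8.35 against 6.70 cycles, while Atp5a1 and Hprt differed by -0.09 and 0.11 cycles. In Ly6d+Gfra2+ CLP it was 6.63 cycles on plate 1 and 10.08 cycles on plate 10, with mean reference Ct of 11.52 and 12.34 cycles. The spike-in Ct therefore cannot decide whether efficiency accounts for part of the differences, and a biological difference between the sorted groups stays open.

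Mpo was detected together with Ebf1 in 56.1% of Ly6d+Gfra2+ CLP (44.7 to 67) and in 10.8% of Gfra2+Bst1- FrA. Ebf1 was detected in 100% of Ly6d+Gfra2+ CLP, so the share there is by construction that of Mpo alone. In Gfra2+Bst1- FrA it also equals the Mpo share. Joint detection was not particular to Ly6d+Gfra2+ CLP, with 48.8% of Ly6d+Gfra2- CLP and 27.6% of Ly6d-Gfra2- CLP. If wells with both held 2 cells, their reference Ct would be lower by about 1 cycle on both plates. It was lower by 0.32 cycles (95% interval over cells -0.06 to 0.70), with 0.54 cycles on plate 1 (-0.00 to 1.09) and -0.00 cycles on plate 10 (-0.45 to 0.44), which argues against pairs of cells as the source in all these wells of both plates, while on plate 1 alone the interval holds 1 cycle and pairs there stay open. Free Mpo RNA from other cells would reach cells with and without Pax5 alike, and the Mpo share differed by -7.01 points between them (-27.5 to 15.2), which leaves that explanation possible for this group. A gradual loss of Mpo transcripts in CLP would leave the same result and was not tested, and the same difference was 48.7 points (14.5 to 59.6) in Ly6d+Gfra2- CLP, 11.6 points (-2.69 to 35.3) in Gfra2-Bst1- FrA and -21.8 points (-52.4 to -0.734) in Gfra2+Bst1- FrA, where 10 cells lacked Pax5.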
